A study of Rattus norvegicus with 6 samples.

How the data were processed

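The study profiled RNA from the neural retina of rats at postnatal day 60 by RNA sequencing. Per the labels, 6 samples fall into 3 groups of 2: Long Evans rats, a pigmented wild-type strain, with sham surgery; Royal College of Surgeons (RCS) rats, a strain whose photoreceptors degenerate, with sham surgery; and RCS rats given human neural progenitor cells (hNPCs) by subretinal injection. Surgery was at postnatal day 21, and sham eyes received the carrier medium alone. Only the part of the retina that held the graft, or the matching part in sham eyes, was used. Per the labels' protocols, RNA was extracted with a column kit and libraries were made with the Ion Total RNA-seq kit, which feeds the Ion Torrent semiconductor sequencers. The labels number the samples within each group, and the titles also carry codes whose numbers run across the RCS groups. They do not say whether the samples are separate animals.

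The table used here is a gene table in the format of Cufflinks, a program that estimates transcript abundance from aligned reads, per the file headers. The authors deposited in it FPKM values (fragment numbers scaled to transcript length in kilobases and to the mapped fragments of the run), with a lower and an upper confidence bound per gene. The submitters' processing notes list Cufflinks 2.0.8 and the rat genome build rn5. The aligner, the annotation release and the confidence level are not given in the sources used here. The rows carry Ensembl gene IDs, and 20601 of the 26406 rows carry a symbol. Its status column reads OK for 26354 rows, LOWDATA for 51 and FAIL for 1.

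The table has one FPKM value per gene, and no column names a sample or a group. It was therefore tied to no sample, and no group was read from its values. The 3 comparisons planned before the data were examined (RCS sham against Long Evans sham, RCS with hNPCs against RCS sham, and RCS with hNPCs against Long Evans sham) were to be fitted with limma on log2 values. They were not run, nor were the tests of opposed changes and of gene lists, because they need a value per library. No mean, standard deviation, fold change between groups or p-value is given anywhere. Each FPKM below rests on the authors' values, from 1 library or 1 pool of libraries; of the genes named, Bcl2l1 is a sum of 2 rows with a computed interval, and the others are deposited values.

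From the table, the following was computed with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1. FPKM of rows that share a symbol were summed, with the interval of a sum taken from the root of the summed squares. The 33 gene lists, holding 715 different genes, were fixed before the data were examined. A list gene was matched by its exact symbol (663 genes), by the same letters in another case (20 genes) or by a synonym in the RefSeq gene table of assembly GRCr8 (4 genes), and 21 genes had no match. Another 7 were further names of a gene already on the list. None of the Ensembl IDs was found in that RefSeq table, so rows without a symbol stay unnamed. For each list the number of members at 1 FPKM or more, the median and the share of the summed FPKM were taken. The median was placed among the medians of 10000 random lists of the same size drawn from all symbols, which describes this table alone. By the rule fixed in advance for lists with no called gene, the text names Mertk first and then the 2 members of each list with the highest FPKM, passing to the next member where an item is not reported here; others are named as chosen after their values were seen.

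The depth is not stated in the sources used here, but the deposited intervals carry it. If an interval spans 2 standard errors on each side and reflects counting error alone, the fragment number behind a gene follows from its FPKM and its upper bound. This implied number was computed for every row above 0. Among 11492 tested rows with an implied number of up to 200, it lay within 0.02 of a whole number in 69.6% (Wilson 95% interval 68.7% to 70.4%), against 3.99% for numbers drawn evenly. Rows whose implied number rounds to 0 were left out of this share. Tested on simulated data, at the FPKM of these same 11492 rows, the calculation recovered 100% of whole numbers as whole and called 0% of non-whole numbers whole. The simulated intervals were built by the same formula, with the non-whole numbers kept further than 0.02 from whole. That outcome was fixed apart from rounding and does not test whether the deposited intervals are counting error. Because whole numbers were more frequent than in even draws, the intervals of rows with up to 200 implied fragments are read as counting error, widened in some rows by other terms. Many genes named below lie above 200 implied fragments. For them the same reading is an assumption that the test does not reach. None of the intervals is read as the spread between animals or libraries. The implied numbers sum to 6124332 fragments over all rows. Intervals widened by isoforms or shared reads make this sum too low. A line was fitted to 5 olfactory receptor rows of known span, kept for a narrow range of spans and for a whole implied number. In them the implied fragments per FPKM rose linearly with span. The slope corresponded to 12304460 mapped fragments, and the intercept to 201 bp taken off the length. FPKM are defined by such a relation, so the linearity does not test whether the intervals are counting error. The slope estimates the number of mapped fragments by which the FPKM values were scaled. Coordinates are those of the table, with starts raised by 1 because its smallest start is 0. FPKM of different genes depend on the transcript models used for length, which are not used here.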

Results

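The series covers retinal RNA from 6 rat samples in 3 groups of 2, made to ask how gene expression differs between degenerating and wild-type retina and how it changes after a graft of human neural progenitor cells. The values analysed here come from 1 table with a single FPKM per gene that names no sample, so they describe the transcript make-up of rat retinal RNA from this series, from 1 library or a pool, and compare genes with one another, not groups. Of 26406 rows, 18154 were above 0, 13900 reached 1 FPKM, 438 reached 100 FPKM and 12 reached 1000 FPKM. After summing rows with a shared symbol, 12135 symbols reached 1 FPKM. The deposited intervals imply 6124332 fragments over all rows.

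Mertk, the phagocytosis receptor gene mutated in the RCS strain, was listed at 4.31 FPKM, with a deposited interval of 3.73 to 4.89 and an implied 223 fragments. Its row (ENSRNOG00000017319) spans positions 128669942 to 128777039 of chromosome 3 in build rn5. The value sums over the whole gene and is tied to no strain here, so it does not check the labels.

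Rod photoreceptor genes stood at the top of the table. Gngt1, the gamma subunit of rod transducin, was at 6641 FPKM (deposited interval 6556 to 6726, an implied 24318 fragments); its row (ENSRNOG00000010546) lies at 28880230 to 28883215 of chromosome 4. Gnat1, the alpha subunit of rod transducin, was at 6316 FPKM (6284 to 6348). Of the 25 genes of the rod phototransduction list, 24 reached 1 FPKM, their median was 469 FPKM (367 FPKM with only the highest row per symbol), and together they held 13.05% of the summed FPKM of the table. The member below 1 FPKM was the row with the symbol Gucy2e, at 0.024 FPKM, named after its value was seen. Which of the symbols Gucy2e and Gucy2d marks the retinal guanylate cyclase in this annotation was not checked. The Gucy2e value is therefore not read as a low level of a rod gene. By implied fragments in place of FPKM, the share of the list was 9.97%. The median of the list exceeded those of all 10000 random lists of its size.

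The second photoreceptor list, of outer segment and structural genes, had all 26 measured members above 1 FPKM, with a median of 155 FPKM. Prph2, a tetraspanin that shapes outer segment discs, stood at 2276 FPKM (2242 to 2310), and its partner Rom1 at 996 FPKM (980 to 1011). Cone genes were present at lower levels: 15 of 16 measured members reached 1 FPKM, with a median of 28.5 FPKM. The highest were Gucy2d, a guanylate cyclase gene, at 60.0 FPKM (57.6 to 62.4) and Gnat2, the cone transducin alpha subunit, at 58.4 FPKM (54.6 to 62.2). Given the open question of its symbol, Gucy2d is not read as a gene of cones alone. The rod list's median was 16.4 times the cone list's.

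Rod genes were set beside their cone counterparts in 8 pairs, chosen after the values had been seen. The rod gene was higher in all 8. The 95% counting intervals of the ratios, which assume deposited bounds at 2 standard errors, all lay above 1. Not all possible counterparts were paired. Gucy2e of the rod list was at 0.024 FPKM and Gucy2d of the cone list at 60.0 FPKM. That pair goes the other way, with its symbols an open question, and was not among the 8. Gnat1 was 108 times Gnat2 (101 to 115), Sag (rod arrestin) was 50.6 times Arr3 (cone arrestin; 46.1 to 55.5), and Pde6b was 42.3 times Pde6c (38.1 to 47.0). Among the channel subunits, Cnga1 was 249 times Cnga3 (173 to 358) and Cngb1 was 23.2 times Cngb3 (19.2 to 27.9). The lowest ratio was that of Gnb1 to Gnb3, at 14.1 (13.2 to 15.1). Gnb1 is also expressed outside rods, and whether Gnb3 is expressed outside cones was not tested here. These ratios compare genes of different transcript lengths within 1 table, and their intervals do not cover the spread between animals or libraries.

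**Figure D1:**
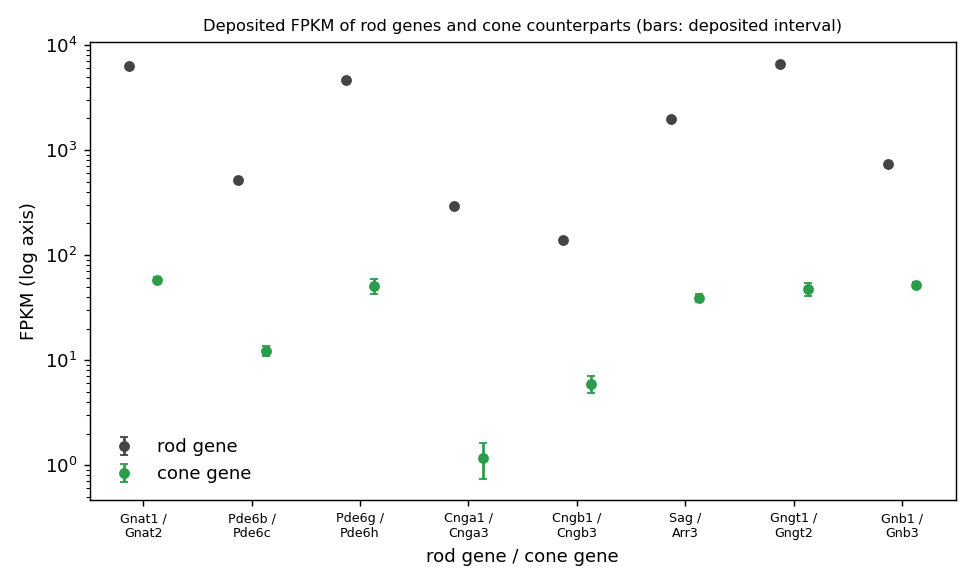
FPKM on a log axis for 8 pairs of a rod gene (grey) and a cone counterpart (green), with bars for the deposited interval; some bars are smaller than the points. The rod gene lies above the cone gene in every pair, from 14.1 times for Gnb1 and Gnb3 to 249 times for Cnga1 and Cnga3. The pairs were chosen after the values had been seen.

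Bipolar, amacrine and ganglion cell genes stood above most genes of the table. All 19 measured bipolar cell genes, all 17 amacrine cell genes and all 17 retinal ganglion cell genes reached 1 FPKM. Their medians were 16.5, 19.0 and 21.8 FPKM. Each median lay above that of more than 99% of random lists (percentiles 99.94, 99.96 and 99.98). Such a place is not particular to retinal cell types, since 14 of the 33 lists lay above the 95th percentile. Among these were circadian clock (percentile 100), oxidative stress response (99.97) and cholesterol synthesis genes (99.39). Pcp2, an ON bipolar cell gene, stood at 113 FPKM (101 to 125) and Gng13 at 109 FPKM (93.9 to 124). Calb2 (calretinin) led the amacrine list at 181 FPKM (174 to 187), and Gad1, which encodes a GABA-synthesizing enzyme, was at 50.8 FPKM (48.5 to 53.2). In the ganglion cell list, Sncg (gamma-synuclein) reached 144 FPKM (135 to 154) and Thy1 reached 123 FPKM (117 to 129). The horizontal cell list was lower, with 7 of 8 members at 1 FPKM or more and a median of 4.79 FPKM (percentile 63.8), led by Tpm3 at 31.0 FPKM (26.1 to 35.8) and the calcium-binding protein gene Calb1 at 23.7 FPKM (21.5 to 26.0). With exact symbols alone, the horizontal cell median was 1.83 FPKM. All 28 members of the synapse list reached 1 FPKM, with a median of 41.5 FPKM, led by Snap25 (a vesicle fusion protein) at 512 FPKM (500.2 to 524) and the vesicular glutamate transporter gene Slc17a7 at 439 FPKM (431 to 448).

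Müller glia, the radial glia of the retina, were represented by 19 of 20 list genes at 1 FPKM or more, with a median of 34.1 FPKM. Glul (glutamine synthetase) stood at 617 FPKM (608 to 627) and Dkk3 at 318 FPKM (311 to 325). The reactive gliosis list had a median of 2.12 FPKM (percentile 30.2) with 18 of 26 members at 1 FPKM or more, led by the intermediate filament gene Vim at 88.4 FPKM (84.2 to 92.6) and the ceruloplasmin gene Cp at 32.8 FPKM (31.1 to 34.6). Gfap, a glial filament gene that is also on the astrocyte list, chosen after its value was seen, was at 8.45 FPKM (7.39 to 9.50). In the astrocyte list, 6 of 10 members reached 1 FPKM, with a median of 5.76 FPKM; Aldoc, a glycolytic enzyme gene, was at 483 FPKM (466 to 500) and the water channel gene Aqp4, also on the Müller list, at 27.9 FPKM (26.5 to 29.3).

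In the microglia and macrophage list, 15 of 32 members reached 1 FPKM and the median was 0.645 FPKM (percentile 4.34). Among its members, Ctss (cathepsin S) was at 16.6 FPKM (14.4 to 18.8) and Lyz2 (lysozyme) at 10.7 FPKM (5.63 to 15.8). Cd68 and Spi1, named after their values were seen, were listed at 0. In the disease-associated microglia list the median was 2.96 FPKM (percentile 46.3; 14 of 23 members at 1 FPKM or more), led by Apoe at 273 FPKM (263 to 283), which Müller glia also express, and the fatty-acid-binding protein gene Fabp5 at 123 FPKM (113 to 132). Of 28 measured T and NK cell genes, 3 reached 1 FPKM and 9 were listed at 0, with a median of 0.131 FPKM (percentile 0.41). Thy1 (123 FPKM), which is also on the ganglion cell list, had the highest value, and Cd4 was at 1.68 FPKM (1.09 to 2.27). The cytokine and chemokine list had a median of 0.171 FPKM (percentile 0.72), with 7 of 27 members at 1 FPKM or more; Il33 stood apart at 59.3 FPKM (56.3 to 62.3), ahead of Cxcl12 at 14.5 FPKM (12.7 to 16.4). Interferon response genes had a median of 0.851 FPKM (percentile 5.45), with 18 of 38 at 1 FPKM or more. Stat2, a signal transducer of type I interferon, was at 8.95 FPKM (8.004 to 9.90) and Ifi27 at 7.69 FPKM (5.72 to 9.67). Complement genes had a median of 1.52 FPKM (percentile 22.7; 11 of 20 at 1 FPKM or more), led by the complement inhibitor gene Cd59 at 65.7 FPKM (61.7 to 69.8) and by C2 at 11.99 FPKM (10.4 to 13.6). Antigen presentation genes had a median of 1.42 FPKM (percentile 18.9; 16 of 27), led by B2m at 36.2 FPKM (33.6 to 38.9) and the class I gene RT1-A2 at 24.5 FPKM (22.1 to 26.9). Several class I RT1 genes resemble one another closely, so the separate value of RT1-A2 is uncertain.

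**Figure D2:**
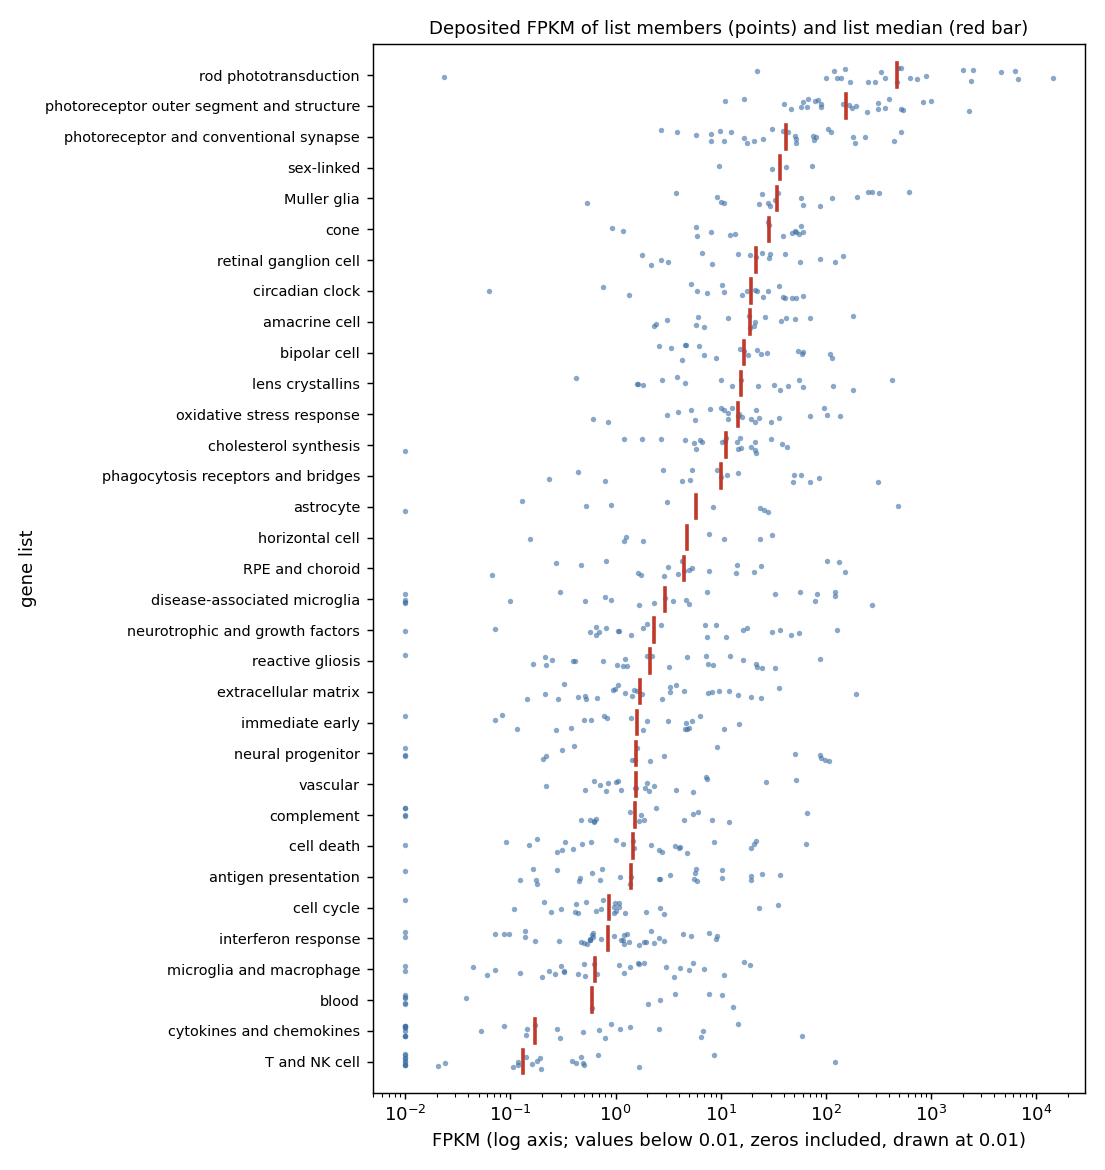
FPKM on a log axis (horizontal) for the members of each of the 33 gene lists (vertical), 1 point per gene, with values below 0.01 drawn at 0.01 and a red bar at the list median. Lists are sorted by median, from 469 FPKM for rod phototransduction to 0.131 FPKM for T and NK cell genes.

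Lists named for tissues beside the neural retina, and for vessels, blood and matrix, also had members at 1 FPKM or more. The source of this RNA was not tested, and being on a list does not show which tissue it came from. The retinal pigment epithelium (RPE) and choroid list had 17 of 21 members at 1 FPKM or more and a median of 4.43 FPKM. Ttr (transthyretin) stood at 152 FPKM (142 to 162) and Ptgds (prostaglandin D synthase) at 103 FPKM (95.3 to 111). Rpe65, the visual cycle isomerase gene of the RPE, chosen after its value was seen, was at 20.7 FPKM (18.8 to 22.5). Of 19 lens crystallin and lens fibre genes, 18 reached 1 FPKM, with a median of 15.6 FPKM (percentile 99.92), led by the alpha-crystallin genes Cryaa at 427 FPKM (411 to 443) and Cryab at 182 FPKM (174 to 189). The vascular list had a median of 1.55 FPKM (15 of 21), with the endothelial receptor gene Kdr at 52.2 FPKM (50.5 to 54.0) and the pericyte gene Rgs5 at 27.1 FPKM (22.1 to 32.2). Blood genes had a median of 0.596 FPKM (6 of 13), and the globin genes Hbb and Hba1 stood at 13.2 FPKM (9.99 to 16.4) and 10.3 FPKM (7.27 to 13.4). Extracellular matrix genes had a median of 1.70 FPKM (20 of 30), led by Sparc at 193 FPKM (187 to 198) and the protease inhibitor gene Timp2 at 36.1 FPKM (33.2 to 38.9). Percentiles among random lists were 67.94 for RPE and choroid, 24.4 for vascular, 13.4 for blood and 21.7 for extracellular matrix genes.

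Lists chosen for the graft and the degeneration were measured as follows. Phagocytosis receptors and their bridging molecules had a median of 10.02 FPKM (14 of 17 at 1 FPKM or more), led by Tulp1, also a photoreceptor gene, at 316 FPKM (308 to 324) and Scarb1 at 86.4 FPKM (81.2 to 91.7). Neural progenitor genes had a median of 1.57 FPKM (11 of 18), led by the RNA-binding protein gene Msi1 at 106 FPKM (99.7 to 113) and the transcription factor gene Pax6, which amacrine and ganglion cells also express, at 97.1 FPKM (92.2 to 102). Dlx1, Dlx2 and Olig2, named after their values were seen, were listed at 0. The grafted cells were human, while these values are for rat genes and tied to no sample. They therefore do not show whether graft cells were present or absent. Neurotrophic and growth factor genes had a median of 2.34 FPKM (17 of 24), led by NXNL1, which encodes the rod-derived cone viability factor, at 127 FPKM (118 to 137) and Vegfa at 55.4 FPKM (52.1 to 58.6). Cell death genes had a median of 1.47 FPKM (16 of 26), led by Bnip3 at 64.9 FPKM (61.1 to 68.8) and the survival gene Bcl2l1 at 21.7 FPKM summed over 2 rows (computed interval 18.4 to 25.004). Oxidative stress response genes had a median of 14.4 FPKM (23 of 25), with Sod1 at 135 FPKM (125 to 145) and GPX4 at 103 FPKM (95.5 to 111).

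The remaining lists cover cholesterol synthesis, cell cycle, circadian clock, immediate early and sex-linked genes. Cholesterol synthesis genes had a median of 11.2 FPKM (22 of 23 at 1 FPKM or more), led by Fdps at 42.2 FPKM (38.3 to 46.2) and Hmgcs1 at 38.4 FPKM (36.3 to 40.4). Cell cycle genes had a median of 0.863 FPKM (9 of 24); Pcna at 34.8 FPKM (31.5 to 38.1) and Tyms at 23.3 FPKM (20.5 to 26.0) were the highest. Circadian clock genes had a median of 19.4 FPKM (18 of 20), with the output gene Dbp at 60.0 FPKM (56.3 to 63.7) and Nr1d1 at 51.7 FPKM (48.3 to 55.0). Immediate early genes had a median of 1.61 FPKM (12 of 22), led by Btg2 at 15.0 FPKM (13.6 to 16.5) and Dusp1 at 10.8 FPKM (9.40 to 12.2). Of the sex-linked list, 4 genes were matched, all X-linked, with a median of 36.4 FPKM, led by DDX3X at 74.5 FPKM (72.2 to 76.8) and Kdm5c at 42.0 FPKM (38.7 to 45.3).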

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

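All settings below marked as added were chosen after the table had been seen. The count of 12135 symbols at 1 FPKM or more stayed within 1.5 times under each of 6 other settings, from 8505 at a minimum of 5 FPKM to 15188 at any value above 0. The share of the rod phototransduction list in the summed FPKM, 13.05%, moved by more than its counting error when only the highest row per symbol was kept (13.2%), with rows at 1 FPKM or more (13.1%), at a minimum of 5 FPKM (13.6%), without rows spanning under 300 bp (added, 14.1%) and with implied fragments in place of FPKM (added, 9.97%). The first 4 settings shrink the summed total. The first also takes 1 of 2 rows from the list member Gnb5, which lowered the list median from 469 to 367 FPKM. Implied fragments are not divided by length. All settings reuse the same fragments, so the counting error is only a yardstick here and does not measure the spread between settings. Of 99 recomputed list medians, 18 differed from the reported value and 1 moved by more than 1.5 times: the horizontal cell list, 2.63-fold, to 1.83 FPKM with exact symbols only (added). Leaving out rows spanning under 300 bp changed none of the list medians, so it says nothing about their stability. No paired analysis was possible because the table holds a single column tied to no sample. For the same reason the other settings set down in advance, which were pseudocount, scaling, quantile normalization, fit of 4 libraries, trend, leaving out a library, threshold, minimum fold, split sham libraries and estimated gene correlation, were not run. Rows with few fragments limit the depth: a value near 1 FPKM in a short transcript rests on a few fragments, and an exact 0 is reported only as listed at 0.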

Other observations

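Gene groups outside the fixed lists were read after the table had been seen, and all tests in this part were chosen after the values they bear on. Among glycolysis genes picked by hand, Aldoa, an aldolase gene, stood at 757 FPKM (deposited interval 743 to 771), Pkm (pyruvate kinase) at 377 FPKM (369 to 384), Ldha (lactate dehydrogenase A) at 361 FPKM (352 to 370) and Hk2 (hexokinase 2) at 187 FPKM, against 34.8 FPKM for Hk1. Of 89 nuclear genes named for the respiratory chain and its assembly, 85 reached 1 FPKM, with a median of 55.0 FPKM; Atp5b stood at 397 FPKM (388 to 406) and Cox4i1 at 241 FPKM (228 to 253). The tubulin gene Tuba1a stood at 307 FPKM (299 to 315). The 85 genes with lower-case ribosomal protein symbols, which include related entries such as Rpl3l and Rps15al1, had a median of 54.0 FPKM. Of these, 79 reached 1 FPKM.

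Within the lens list, levels were uneven. The beta-crystallin gene Crybb2 was at 118 FPKM (109 to 126) and Crygs at 43.9 FPKM (38.5 to 49.2), while the lens fibre genes Mip and Lim2 were at 1.60 FPKM (0.743 to 2.45) and 1.81 FPKM (0.844 to 2.78). Among pigment cell genes, Tyrp1 was at 14.2 FPKM (12.8 to 15.6), Dct at 14.0 FPKM (12.04 to 15.9) and Tyr at 0.471 FPKM (0.238 to 0.705). No explanation was tested for either set.

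All 37 rows of the mitochondrial chromosome were listed at 0, among them the cytochrome oxidase and ribosomal RNA genes, beside the nuclear respiratory genes at a median of 55.0 FPKM. All 92 rows on 73 unplaced contigs were at 0 as well, whereas 69.1% of rows on the numbered chromosomes and X were above 0. In 10000 draws of chromosome rows matched on span and on having a symbol, at least 27 of 92 were above 0, with a median of 45. A difference in sequence names between the annotation and the aligned genome is a candidate explanation that covers both sets. Removal of mitochondrial reads before quantification stays open for the mitochondrial rows, since the 92 contig rows, which it would not reach, say nothing about it; no biological explanation was tested.

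Short rows stood among the highest values: 11 of the 40 rows with the highest FPKM spanned under 300 bp. The 32 rows of up to 150 bp at 100 FPKM or more, 22 of them without a symbol, held 4.82% of the summed FPKM on a median of 6.0 implied fragments. Scaled by their full span in place of an effective length, their median was 6.03 FPKM, but this only restates the low fragment numbers, since all 32 rows are shorter than the 201 bp estimated to be taken off the length. That high FPKM on few implied fragments go with a short effective length follows from the definition of FPKM. The rescaling does not test it, and the effective lengths of these rows were not known. Whether the RNA of these rows is abundant but was mostly lost in library preparation stays open.

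The same test, with rows rounding to 0 fragments left out, was applied to ribosomal protein rows with up to 200 implied fragments. They carried whole numbers less often than others: 5 of 85 (5.88%, Wilson 95% interval 2.54% to 13.04%) against 78.1% of 9184 other rows with a symbol. Of the 38 spanning under 600 bp, 0 gave a whole number (up to 9.18%), against 127 of 228 other short rows with a symbol (55.7%, 49.2% to 62.0%) and 94 of the 133 among these with mixed-case symbols (70.7%). Reads divided between near-identical copies may account for the short rows, and 3 of 6 rows named RPL39 had the same value, 412.745 FPKM. Several isoforms per gene also widen intervals. If short rows leave little room for isoforms, this would treat both classes alike. The isoforms of these rows were not known here, so their part in the gap between short rows was not settled. A GAPDH row of 1272 bp on chromosome 5 was listed at 556 FPKM, 3.65 times the 152 FPKM of the Gapdh row on chromosome 4, and UBB stood at 2103 FPKM; levels of such genes are uncertain in this table.

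The implied fragments of all rows came to 49.8% of the 12304460 mapped fragments estimated to lie behind the scaling of the FPKM values.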
